A study of Marmota monax with 18 samples.

How the data were processed

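Total RNA of 3 carcinomas and of the 3 matching surrounding liver samples was converted to biotin-labelled cRNA and read on Affymetrix chips made for human, rat and mouse, 6 arrays per chip. Per the labels' protocols, a pathologist separated tumour from non-cancerous liver, and the tissues were snap-frozen. The deposited values are probe set signals, an intensity on a linear scale with 1 value per probe set and array, made with GCOS 1.2 per the submitters' processing notes. The signal algorithm, its background step and the scaling target are not given in the sources used here. The mean after trimming 2% at each end over all probe sets was 15.0 on every human and rat array, so these were used as deposited. On the mouse chip it was 15 on 1 array (adjacent liver of 6361) and between 8.78 and 11.3 on the other 5. The plan fixed before the data were examined was to use all signals as deposited. Since the deposited mouse arrays did not share a scale, each was multiplied to a trimmed mean of 15. This choice was made on seeing the array means and before any test, and the signals as deposited became an alternative.

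The tables held 54675 human, 31099 rat and 45101 mouse probe sets, of which 62, 57 and 64 are controls and were left out of the tests. By the platform annotation, 41091 human, 20826 rat and 34945 mouse probe sets have 1 gene symbol, 1801, 436 and 932 have several, and 11721, 9780 and 9160 have none. Genes were named only from probe sets with 1 symbol and matched between chips by symbol in capitals. Of the 4953 genes tested in the 3-chip average, 4800 symbols (79 of the 81 past the threshold) are also in the annotation of the woodchuck assembly, which was used for names alone. Woodchuck sequence was not compared with the probes, so that binding to a related transcript cannot be excluded for any probe set.

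Signals were analysed as log2(signal + pseudocount), the pseudocount being the 25th percentile of the chip's signals (2.76 for human, 3.00 for rat, 3.26 for mouse). Differences are on this scale, which understates the change of dim genes. Probe sets with a mean log2 value above the chip's median were tested. Each chip was fitted separately with limma 3.58.1 in R 4.3.3, with the animal as a block, an empirical Bayes prior with trend, and Benjamini-Hochberg adjustment at 0.05. For the 3-chip average, the probe set with the highest mean signal stood for a gene on each chip, genes had to pass the filter on all 3 chips, and the 3 values of a tissue were averaged before the same fit. Residual degrees of freedom were 2, and the prior added 16.2 (human), 12.5 (rat), 11.8 (mouse) and 90.1 (3-chip average), so that most of the error estimate in the average came from other genes. The pairing comes from the animal numbers in the labels and the stated design of 3 pairs. The deviations from the group means of the 2 tissues of an animal correlated at 0.0768 (5904), 0.088 (6337) and 0.151 (6361) in the 3-chip average. Those of different animals had negative means, which follow from centring on the mean of 3 animals and add nothing on the pairing.

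Gene lists, 24 in number, were fixed before the data were examined and tested with limma's camera (preset correlation 0.01, lists with 5 or more tested genes, Benjamini-Hochberg over lists). Chips were compared by limma on the per-animal differences, and by correlations across genes. Brightness was compared by an exact sign-flip permutation test over the 6 tissues, and again over the 3 animals. The genes named were fixed by rule. For the 3-chip average these are the 10 largest rises and 10 largest falls among genes past the threshold with 1 sign in all 3 animals. For each chip they are 5 and 5 by the same rule, filled by the smallest p where too few passed, and for each list up to 4 members with the smallest p. A set of 11 liver cancer genes was always named where measured, of which 1 is not reported here. Genes named beyond this rule were chosen after their values were seen, and the text says so where they appear.

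The alternatives tried were quantile normalization, other pseudocounts, other filters, no block, no trend, each animal left out, each chip left out, the mean of a gene's probe sets, genes present on 2 chips, and other list tests. Added after seeing the data were the brightness test over animals, mouse signals as deposited, the average without the mouse-chip pair of 5904, lists on single chips and lists over genes on at least 2 chips. The fits were tested on simulated data with 200 genes or probe sets changed. The 3-chip fit on 4953 genes recovered 53% of those changed by 1 on the log2 scale and 99% of those changed by 2. The human fit on 27306 probe sets recovered 0% and 40%, the rat fit on 15521 probe sets 5% and 43%, and the mouse fit on 22518 probe sets 1% and 33%. The test of chip differences (human minus rat, 4953 genes) recovered 6% at a difference of 1.5 and 79% at 3. Of the unchanged genes or probe sets, 6 (3-chip average), 2 (human), 6 (rat) and 1 (mouse) were called. Camera found a list shifted by 0.5 and called 0 others. Noise was normal and drawn independently for each gene, with the moderated variances of the fits, so the recovered shares hold for such noise only. Since the simulated genes were not correlated, the run cannot show false calls of lists whose genes are. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.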

Results

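Liver carcinomas and the liver around them were taken from 3 woodchucks (Marmota monax) that had been infected with woodchuck hepatitis virus at birth. RNA of each of the 6 tissues was hybridised to a human, a rat and a mouse Affymetrix expression chip, so that 18 arrays were read. Probes of these chips were designed for other species, and how well they bind woodchuck transcripts was not measured. The series asked how the human, rat and mouse chips compare when woodchuck tumour and surrounding liver are hybridised to each under the same conditions. The animals carry the numbers 5904, 6337 and 6361, and each gave 1 carcinoma and 1 adjacent sample. The 3 arrays of a tissue are repeat readings of the same sample, so every comparison rests on n = 3 animals, and this number limits the precision.

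Few probe sets gave a bright signal with woodchuck RNA. On the human chip 1.23% ± 0.33 (SD, n = 6 arrays) of the probe sets were brighter than the bacterial bioB spike-in controls, which mark the lower end of the spiked range. The rat chip gave 0.587% ± 0.223 (SD, n = 6), and the mouse chip 1.34% ± 1.03 (SD, n = 6). The human chip exceeded the rat chip in 6 of 6 tissues (two-sided exact sign-flip permutation test, p = 0.0312, adjusted p = 0.0469 over 3 comparisons). The mouse chip also exceeded the rat chip in 6 of 6 tissues (exact p = 0.0312, adjusted p = 0.0469), and 0.0312 is the smallest p that 6 pairs allow. The 6 tissues come from 3 animals and are not independent. With the tissues of an animal averaged, both differences had the same sign in 3 of 3 animals and did not pass (exact p = 0.25, the smallest that 3 animals allow). The human share was above the mouse share in 5 of 6 tissues (exact p = 1). The mouse array of the carcinoma of animal 5904 stood alone at 3.43%, with a mean bioB signal of 36.3 against 103 to 233 on the other mouse arrays. These bioB values are deposited signals without a shared scale. The trimmed mean was 8.78 on that array and 8.92 to 15 on the other mouse arrays. With the upper end of the B. subtilis control probe sets as the threshold, the human share exceeded the mouse share in 6 of 6 tissues (exact p = 0.0312).

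**Figure D1:**
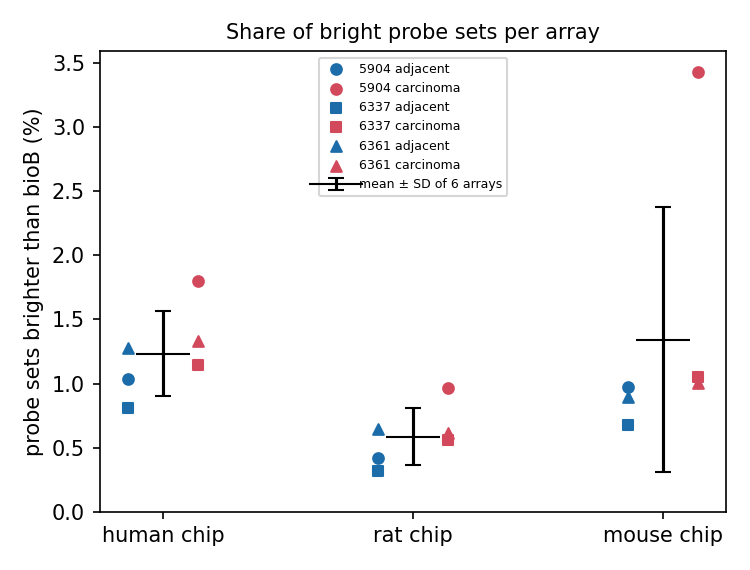
Percent of probe sets brighter than the mean of the bioB control probe sets (y axis) on each array of the human, rat and mouse chip (x axis). Each point is 1 array, blue for adjacent liver and red for carcinoma, with 1 marker shape per animal; horizontal bars are means and whiskers 1 SD of 6 arrays. Rat arrays lie between 0.319% and 0.966%, and 1 mouse array, the carcinoma of animal 5904, lies at 3.43%.

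The question was which genes differ between carcinoma and adjacent liver in the average of the 3 chips. Each SE in these results is that of the limma fit, which comes mostly from other genes. It does not measure the spread between the 3 animals, and the adjusted p rests on it. NT5DC2, a protein with a nucleotidase domain, rose by a log2 difference of 2.57 ± 0.28 (SE, n = 3), a 5.95-fold higher signal (adjusted p = 1.65e-11). EEF1A2, the elongation factor isoform normally made in muscle and neurons, was 5.26-fold higher (log2 difference 2.40 ± 0.36, SE, n = 3, adjusted p = 8.57e-07). Its log2 differences were 4.40 in animal 5904, 2.35 in 6361 and 0.44 in 6337, with an SD of 1.98 between animals. COL1A1, a chain of fibrillar collagen, was 3.46-fold higher (log2 difference 1.79 ± 0.25, SE, n = 3, adjusted p = 1.48e-07). HKDC1, a hexokinase, rose by 1.48 ± 0.33 (adjusted p = 0.00289), ELOVL6, a fatty acid elongase, by 1.30 ± 0.36 (adjusted p = 0.0412), and SPNS2, a sphingolipid transporter, by 1.28 ± 0.28 (adjusted p = 0.00289). LZTS3 (1.62), RNF7 (1.59), a RING subunit of ubiquitin ligases, CXXC4 (1.52), an inhibitor of Wnt signalling, and NINJ2 (1.44), an adhesion protein, make up the 10 genes with the largest rise, and all 10 were higher in 3 of 3 animals. The rise of HKDC1 came from the human chip, with a log2 difference of 3.69 there against 0.04 on the rat chip and 0.72 on the mouse chip, although the difference between chips was not past the threshold for any gene. ELOVL6 likewise had 2.76 on the human chip, 0.53 on the rat chip and 0.62 on the mouse chip. COL1A1 (2.36) and SPNS2 (1.42) were largest on the rat chip and RNF7 (2.24) on the mouse chip. The other named rises were largest on the human chip. Without animal 5904 EEF1A2 (1.39, adjusted p = 0.173), CXXC4 (1.45, adjusted p = 0.0514), HKDC1 (1.26, adjusted p = 0.0992), NINJ2 (1.23, adjusted p = 0.28) and ELOVL6 (1.06, adjusted p = 0.42) lost their call. Without 6361 SPNS2 (1.19, adjusted p = 0.0926), NINJ2 (1.49, adjusted p = 0.162) and ELOVL6 (1.15, adjusted p = 0.33) lost it, and without 6337 EEF1A2 had 3.37.

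EGR1 had the largest fall of the genes past the threshold in that average. EGR1, an immediate-early transcription factor, fell by 2.69 ± 0.25 on the log2 scale (SE, n = 3), a 6.45-fold lower signal (adjusted p = 2.92e-14). JUNB, a subunit of the AP-1 factor, fell by 1.79 ± 0.26 (adjusted p = 8.02e-07), and ETS1, another transcription factor, fell by 1.40 ± 0.25 (adjusted p = 0.00019). IGFBP2, a binding protein of insulin-like growth factors, was 4.53-fold lower (log2 difference -2.18 ± 0.26, adjusted p = 4.86e-10). SAT1, which acetylates polyamines, was 4.29-fold lower (log2 difference -2.10 ± 0.27, adjusted p = 2.36e-08). RBMS1, an RNA-binding protein, was 3.63-fold lower (log2 difference -1.86 ± 0.25, adjusted p = 7.46e-08). PPARGC1A, a coactivator of mitochondrial and gluconeogenic genes, fell by 1.49 ± 0.29 (adjusted p = 0.000464). APBB1 (-1.60), CERS2 (-1.51), a ceramide synthase, and SEMA6D (-1.46), a semaphorin, complete the 10 largest falls, each lower in 3 of 3 animals. Without animal 5904 CERS2 (-1.27, adjusted p = 0.271), PPARGC1A (-0.89, adjusted p = 0.163) and ETS1 (-0.92, adjusted p = 0.0575) lost their call, and without 6361 APBB1 (-1.29, adjusted p = 0.0804), CERS2 (-1.59, adjusted p = 0.0915) and SEMA6D (-1.15, adjusted p = 0.224) did.

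**Figure D2:**
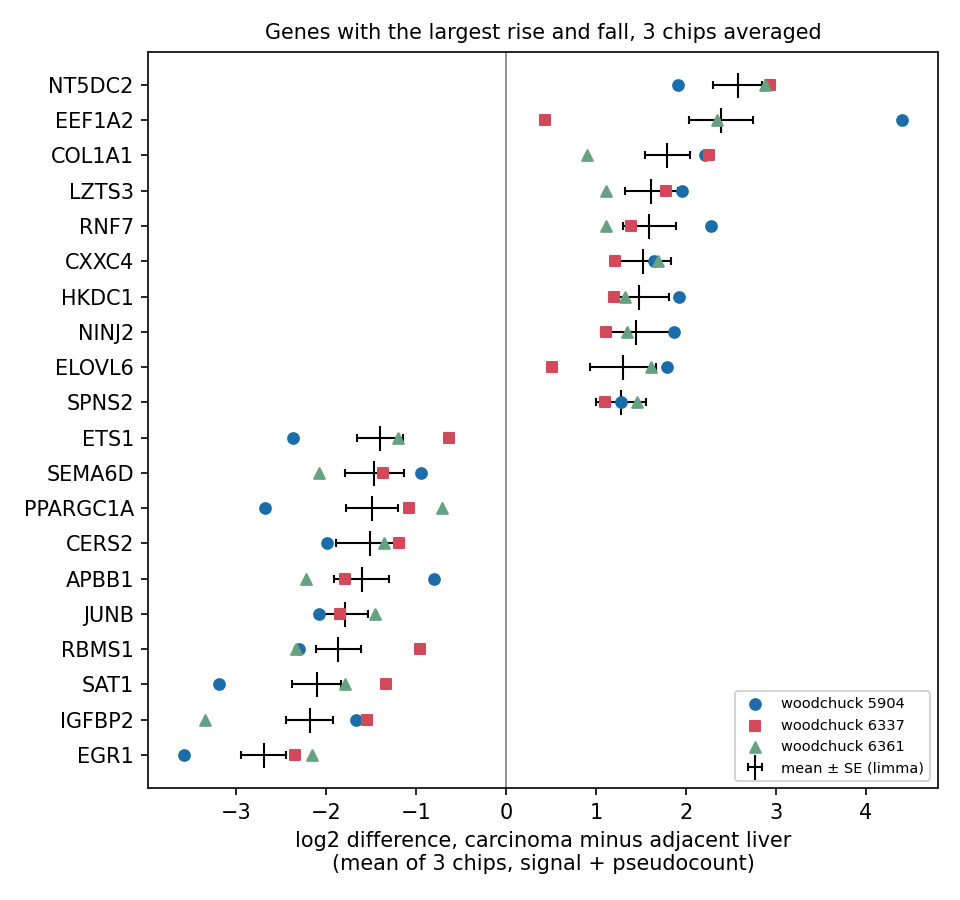
Log2 difference between carcinoma and adjacent liver (x axis, mean of 3 chips) for the 10 genes with the largest rise and the 10 with the largest fall among those past adjusted p 0.05 with 1 sign in all 3 animals (y axis). Coloured points are the 3 animals, black ticks the means and whiskers the standard error of the limma fit. EEF1A2 has the widest spread among the rises, from 0.44 to 4.40, and all points of EGR1 lie at or below -2.16.

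In all, 81 of the 4953 genes tested on all 3 chips were past adjusted p 0.05 in the paired limma fit, 39 higher and 42 lower in carcinoma, and 534 had an unadjusted p under 0.05. By chance a share of 0.05 of the genes or probe sets tested has such an unadjusted p, here and on each chip. Of the 81 genes, 79 had the same sign in the 3 animals and 75 (92.6%) had the same sign on the 3 chips, where 30.8% of all tested genes did and chance gives 25%. The 81 genes were picked on the average of these chips, so that their shared sign is not independent evidence. Without the pairing of tissues by animal (no block) the count was 15, without the trend in the prior variance 18, without the human chip 2, without the rat chip 31, with mouse signals left as deposited 26, with a pseudocount of 1 it was 51, with no filter on low signals 39, and with the mean of a gene's probe sets 32. Leaving out animal 5904 gave 43 genes and leaving out 6361 gave 33, while quantile normalization gave 63, of which 33.3% were higher against 48.1% of the 81.

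Lists of hepatocyte genes gave 4 calls, all lower in carcinoma, that were made only with camera's preset correlation of 0.01 between genes. With an estimated correlation camera also rests on the 2 residual degrees of freedom, and the smallest adjusted p of any list was 0.414. The estimate for plasma protein genes was -0.0256, under the preset, so correlation between genes does not explain the loss of that call. None of the 4 passed with an estimated correlation (adjusted p = 0.414 each) or in fry, which asks whether a list moves on balance one way (adjusted p from 0.148 to 0.345). Xenobiotic, gluconeogenesis and fatty acid oxidation genes did not pass even with the preset correlation. Of 17 tested plasma protein genes 15 had a negative difference, the list median was -0.42, and camera gave an adjusted p = 2.62e-05 (estimated correlation, adjusted p = 0.414). In it ITIH1, which binds hyaluronan, fell by 1.23 ± 0.24 (SE, n = 3, adjusted p = 0.00057), and ceruloplasmin, CP, fell by 0.84 ± 0.24 (adjusted p = 0.0471), a call lost without any 1 animal (adjusted p from 0.111 to 0.389). By chip, ITIH1 had -1.27 (human), -1.24 (rat) and -1.18 (mouse), while CP had -1.03, -1.53 and 0.03. RBP4, the retinol carrier (-0.81, adjusted p = 0.0826), and ITIH3 (-0.70, adjusted p = 0.146) did not pass, so 2 of the 17 passed over all genes and 4 when adjusted over the list alone. Of 17 genes of the urea cycle and amino acid catabolism 13 were lower, with a list median of -0.43 (camera adjusted p = 0.00447). ASS1, argininosuccinate synthase, differed by -2.69 in animal 5904, -0.23 in 6337 and -0.16 in 6361, a mean of -1.03 ± 1.44 (SD, n = 3, adjusted p = 0.0432), and without 5904 it had -0.20 (adjusted p = 0.878). By chip, ASS1 had -1.92 (human), -0.96 (rat) and -0.20 (mouse). CPS1, the first enzyme of the cycle, had -0.96 (adjusted p = 0.0585). In this list 1 gene passed over all genes and 2 when adjusted over the list alone. All 5 tested beta-catenin target genes of liver had negative differences (median -0.60, camera adjusted p = 0.00208), led by CYP2E1, a cytochrome P450 of the pericentral zone, which fell by 1.14 ± 0.28 (adjusted p = 0.0124) and lost its call without 6337 (adjusted p = 0.228) or 6361 (adjusted p = 0.35). GLUL, glutamine synthetase, had -0.84 (adjusted p = 0.0542), and in this list 1 gene passed over all genes and 2 when adjusted over the list alone. The acute phase list was lower too (8 of 9 genes, median -0.46, camera adjusted p = 0.0235), with 0 genes past over all genes and 4 when adjusted over the list alone. Of those 4, HP (-0.75), SOCS3 (-0.86) and A2M (-0.65) had negative differences and IL6ST had 0.85.

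With the preset correlation 3 lists were called higher, and none of them passed with an estimated correlation or in fry (adjusted p from 0.21 to 0.532). The estimated correlation was 0.47 for ribosomal protein genes, -0.047 for cell cycle genes and -0.0663 for glycolysis genes. Cytosolic ribosomal proteins had 16 of 17 positive differences with a median of 0.41 (camera adjusted p = 7.47e-05, with an estimated correlation adjusted p = 0.455). In the 3-chip average the list median was 0.87 in animal 6337, 0.61 in 6361 and -0.49 in 5904. On the rat chip alone, with 40 tested members, it was above 0 in all 3 animals, at 0.95, 0.82 and 0.22, while in animal 5904 it was -0.12 on the human chip (50 members) and -0.41 on the mouse chip (40 members). No ribosomal gene passed over all genes and 3 passed when adjusted over the list alone, RPL22 (0.93), RPL35 (0.88) and RPL41 (0.85). Cell cycle and DNA replication genes were higher in 14 of 22 (median 0.40, camera adjusted p = 0.0443, with an estimated correlation adjusted p = 0.414). The median of these members was 0.80 on the human chip, 0.03 on the rat chip and -0.03 on the mouse chip, and without the human chip the list did not pass (adjusted p = 0.26). CKS2, a subunit of cyclin-dependent kinases, was 2.30-fold higher (adjusted p = 0.00193, without 6361 adjusted p = 0.15), UBE2C had 1.10 (adjusted p = 0.0704), CCNE1 had 1.14 (adjusted p = 0.13) and FEN1 had -0.78 (adjusted p = 0.16). In this list 1 gene passed over all genes and 5 when adjusted over the list alone, 4 of them higher. Glycolysis genes were higher in 7 of 8 (median 0.27, camera adjusted p = 0.0434, with an estimated correlation adjusted p = 0.414), with PGK1, phosphoglycerate kinase, up by 0.99 ± 0.26 (adjusted p = 0.0267, without any 1 animal adjusted p from 0.0879 to 0.246) and LDHB at 0.80 (adjusted p = 0.198). By chip, PGK1 had 1.93 (human), 0.95 (rat) and 0.11 (mouse). In this list 1 gene passed over all genes and 2 when adjusted over the list alone.

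Of the 7 calls by list, plasma proteins, beta-catenin targets, acute phase and ribosomal proteins passed without animal 5904. Plasma proteins, urea cycle and acute phase passed without 6337, and plasma proteins without 6361, so that none of the 3 higher lists passed without 6337 or without 6361.

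The other 16 of the 23 lists with at least 5 tested genes were not past the threshold. Xenobiotic and bile acid genes had a median of -0.17 (camera adjusted p = 0.0588), interferon-stimulated genes of -0.24 (adjusted p = 0.0765) and stellate cell and matrix genes of 0.20 (adjusted p = 0.105). In the matrix list, 2 genes passed over all genes and 3 when adjusted over the list alone, COL1A1, COL4A1 (0.95, without 6337 0.42 with adjusted p = 0.75) and CYGB (1.01). Gluconeogenesis genes had a median of -0.30 with 8 of 8 negative (adjusted p = 0.138), and fatty acid oxidation had -0.21 (adjusted p = 0.138), where ETFB, an electron transfer flavoprotein subunit, fell by 1.01 ± 0.24 (adjusted p = 0.0109, without 6337 adjusted p = 0.0879 and without 6361 adjusted p = 0.404). Lipogenesis and cholesterol synthesis had 0.13 (adjusted p = 0.234), with ELOVL6 past the threshold and FADS2, a desaturase, at 0.91 (adjusted p = 0.104). Markers of fetal liver and carcinoma had a median of -0.27 (adjusted p = 0.177), the mitochondrial respiratory chain -0.07 (adjusted p = 0.234) and the proteasome 0.14 (adjusted p = 0.491). Heat shock proteins had 0.05 (adjusted p = 0.659) and secretory chaperones -0.07 (adjusted p = 0.733), with SEC61B of the translocon up by 0.85 ± 0.24 (adjusted p = 0.0471, without any 1 animal adjusted p from 0.0754 to 0.619). Markers of other cell types did not pass. T and NK cell markers had a median of -0.23 (adjusted p = 0.353), macrophages -0.05 (adjusted p = 0.584), B and plasma cells 0.13 (adjusted p = 0.584), endothelium 0.19 (adjusted p = 0.352) and cholangiocytes 0.15 (adjusted p = 0.508). The red blood cell list had only 3 tested genes and no test, with a median of -0.14.

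**Figure D3:**
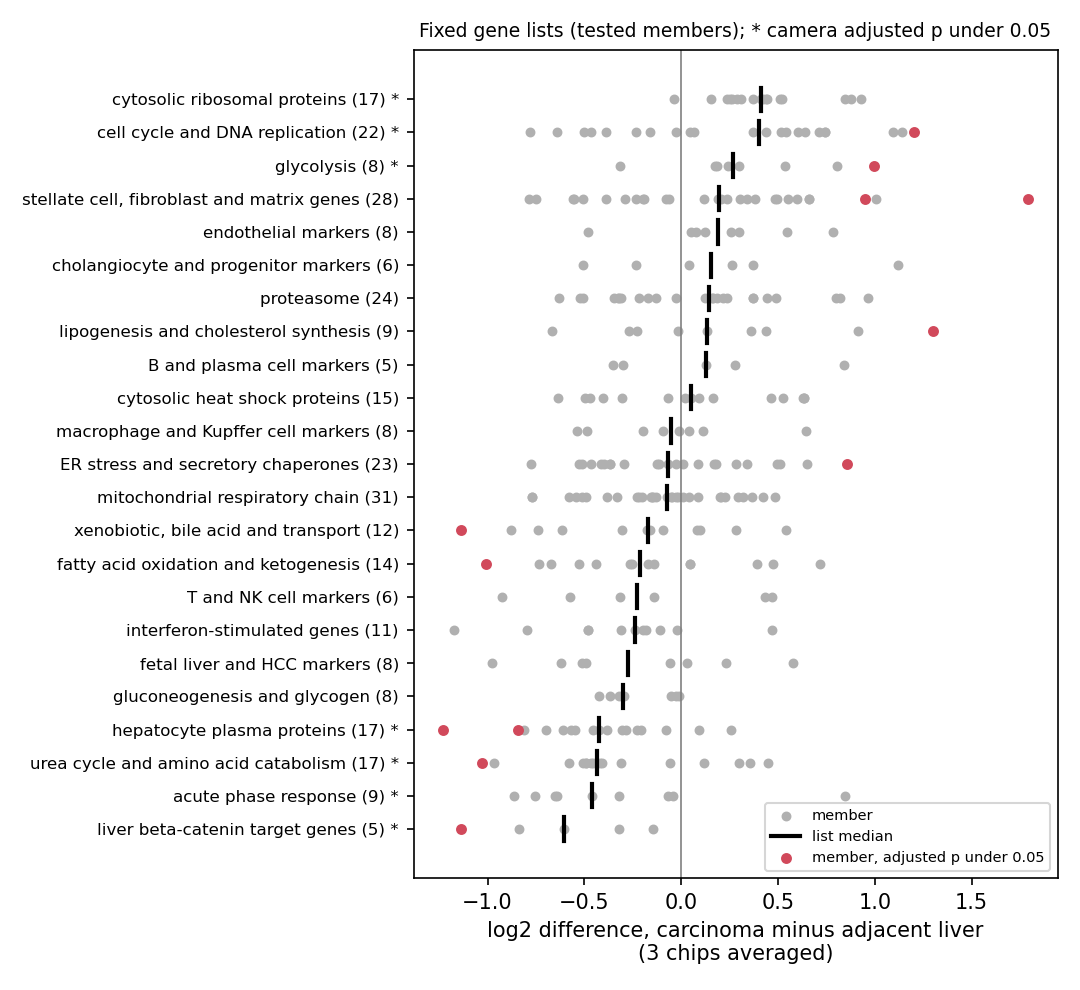
Log2 difference between carcinoma and adjacent liver (x axis, mean of 3 chips) of each tested member of the 23 fixed gene lists (y axis, number of members in brackets). Grey points are members not past adjusted p 0.05, red points members past it, black ticks list medians, and an asterisk marks camera adjusted p under 0.05 with the preset correlation. Medians run from -0.60 for beta-catenin targets to 0.41 for ribosomal proteins.

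On the human chip by itself FABP4, a fatty acid binding protein of adipocytes and endothelium, rose by 3.76 ± 0.55 on the log2 scale (SE, n = 3, adjusted p = 0.00395), and SCD, stearoyl-CoA desaturase, rose by 3.25 ± 0.47 (adjusted p = 0.00333). HKDC1 (3.69), NT5DC2 (3.65) and EEF1A2 (2.96) were the other genes named among the rises. Signals of FABP4 and HKDC1 were dim in adjacent liver (mean log2 3.16 and 2.56), so that their size depends on the pseudocount, from 3.09 to 4.13 for FABP4 and 2.86 to 4.17 for HKDC1. NT5DC2 and EEF1A2 in adjacent liver (mean log2 3.36 and 3.46) and IGF2BP2 in carcinoma (3.36) were nearly as dim, and the same limit holds for them. EGR1 was 15.1-fold lower (log2 difference -3.91 ± 0.34, adjusted p = 1.98e-05) and IGFBP2 14.7-fold lower (-3.88 ± 0.36, adjusted p = 3.92e-05). The metallothionein genes MT1X and MT1H, which bind zinc and copper, fell by 3.26 ± 0.54 (adjusted p = 0.00907) and were 8.58-fold lower (adjusted p = 0.0018), and copies of this family are near-identical, so that the member cannot be named with certainty. IGF2BP2, an RNA-binding protein, fell by 3.07 ± 0.49 (adjusted p = 0.00654). Without animal 5904 FABP4 had 2.79, SCD 2.46, MT1X -2.10 and MT1H -2.30, and EEF1A2 lost its call (2.28, adjusted p = 0.27). Without 6337 SCD had 4.11, MT1X -4.17 and MT1H -3.93, and without 6361 FABP4 had 4.58 and IGFBP2 -3.15. In total 68 of 27306 probe sets passed, 33 higher and 35 lower, and they name 53 genes. The count was 31 without the pairing (no block), 0 without the prior trend, 18 with no filter, 29 with the stricter filter, 233 without animal 5904 and 112 without 6361.

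On the rat chip 1 of 15521 probe sets passed, that of RBMS1, which fell by 2.19 ± 0.29 on the log2 scale (SE, n = 3, adjusted p = 0.0375), and 1092 had an unadjusted p under 0.05. EGR1 (-2.13, adjusted p = 0.0588), GMPPA (-2.57, adjusted p = 0.0588), a regulatory subunit of the enzyme that makes GDP-mannose, CP (-1.53, adjusted p = 0.163) and SULT1A1 (-1.99, adjusted p = 0.232), a sulfotransferase, had the next smallest p among the lower genes. COL1A1 had the smallest p among the higher genes (2.36, adjusted p = 0.0588), ahead of TPM1 (1.66, adjusted p = 0.0843), a tropomyosin. PCNA (1.41), the replication clamp, H2AZ1 (1.42), a histone variant, and PPP2R5E (1.40), a phosphatase subunit, each had an adjusted p = 0.232. The call of RBMS1 was lost without the pairing (no block, 0 probe sets), without the prior trend (0), with pseudocount 1 (0) and with the stricter filter (0), while quantile normalization gave 5, no filter 5 and the median as pseudocount 4. Leaving out an animal gave 41 (5904), 7 (6337) and 44 (6361).

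On the mouse chip 0 of 22518 probe sets passed in the limma fit, the smallest adjusted p being 0.0716, and 1467 had an unadjusted p under 0.05. LBP, the lipopolysaccharide binding protein of plasma, had the largest difference of the named genes (-3.12 ± 0.44, SE, n = 3, adjusted p = 0.0716). CNN3 (-2.05, adjusted p = 0.206), EGR1 (-2.02, adjusted p = 0.206), TTC36 (-1.85, adjusted p = 0.256) and ZFAND5 (-1.95, adjusted p = 0.256) followed. The higher genes with the smallest p were METTL26 (2.01, adjusted p = 0.2), PSMB5 (1.82, adjusted p = 0.256), a proteasome subunit, TKT (1.89, adjusted p = 0.256), transketolase, SYNCRIP (2.02, adjusted p = 0.287) and NT5DC2 (2.70, adjusted p = 0.383). The median as pseudocount gave 2 calls and signals left as deposited gave 11. Leaving out an animal gave 157 (5904), 43 (6337) and 11 (6361).

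By size alone, 531 human-chip probe sets differed at least 2-fold the same way in all 3 animals, 239 higher and 292 lower, against 354, 315 and 324 when the pair of 1 animal was turned round. The rat chip had 209 (95 higher, 114 lower) against 135, 140 and 144, and the mouse chip 293 (132 higher, 161 lower) against 212, 208 and 193. With mouse signals as deposited the mouse count was 292, of which 107 were higher and 185 lower. In the 3-chip average 17 genes met the criterion, 9 higher and 8 lower, against 3, 2 and 1. These counts have no p-value. The filter and the pseudocount moved them by over 1.5 times: on the human chip the median as pseudocount gave 244, no filter 891 and the stricter filter 214.

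Effects of carcinoma correlated weakly between chips, and also between animals on the same chip. Across the 4953 genes the mean differences correlated at Pearson r = 0.14 (Spearman 0.126) between human and rat chips, 0.111 (0.0952) between human and mouse chips and 0.0776 (0.0739) between rat and mouse chips. Genes are not independent replicates, so that these values describe the chips. The difference of the same animal correlated at a mean r of 0.0773, 0.0563 and 0.0487 in the 3 pairs of chips, and that of other animals at 0.0457, 0.0404 and 0.0233. On the same chip, the differences of different animals correlated at 0.112 to 0.142 (human), 0.0704 to 0.0985 (rat) and 0.0588 to 0.0848 (mouse), so that the low values are not shown to be a difference between chips. No gene differed between chips in the carcinoma effect at adjusted p 0.05 by limma, and 355 (human minus rat), 335 (human minus mouse) and 323 (rat minus mouse) had an unadjusted p under 0.05. Leaving out animal 5904 gave 8 genes. By chance a share of 0.05 of the 4953 genes has an unadjusted p under 0.05. In simulated data the human-minus-rat test recovered 6% of differences of 1.5 and 79% of those of 3. The lack of calls therefore does not show that the chips give equal effects. Among the 81 genes past the threshold r was 0.77, 0.772 and 0.737, values raised by the choice of these genes on the average of the same chips.

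Of the liver cancer genes named in advance, CYP2E1 passed in the 3-chip average (-1.14, adjusted p = 0.0124) and on the human chip (-1.88, adjusted p = 0.0173), and the others measured did not. AFP, alpha-fetoprotein, had a log2 difference of 1.87 ± 1.94 (SD, n = 3) on the human chip (adjusted p = 0.337), with 3.60 in animal 5904, 2.23 in 6337 and -0.23 in 6361. Its mouse probe set gave 0.07 ± 1.57 (SD, n = 3), and its rat probe set was under the filter. GPC3, a glypican of fetal liver, had -0.62 in the 3-chip average (adjusted p = 0.578). MYCN, a proto-oncogene, had -0.98 ± 1.82 (SD, n = 3, adjusted p = 0.23), with -2.81 in 5904, -0.94 in 6337 and 0.82 in 6361. IGF2 had 1.43 ± 0.50 (SD, n = 3) on the mouse chip (adjusted p = 0.475) and -0.36 ± 1.15 on the rat chip (adjusted p = 0.922). On the human chip MYC had a mean log2 signal of 5.42 in carcinoma and 6.42 in adjacent liver (adjusted p = 0.581). MKI67, a proliferation antigen, differed there by 0.43 ± 0.89 (SD, n = 3, adjusted p = 0.889) and SPP1, osteopontin, by -0.63 ± 1.18 (SD, n = 3, adjusted p = 0.873). ALB, albumin, differed by -0.08 in the 3-chip average (adjusted p = 0.971).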

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

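The search of control probe sets was chosen after the data were examined, and the splits of the samples before. Control probe sets outside the comparisons were searched for families over 2-fold higher in the tumour arrays than in the adjacent arrays of an animal on every chip that carries them, for families on at least 2 chips, and 4 were found. Lower families and those on 1 chip were not searched, such as the 5S ribosomal RNA, carried by the rat chip alone, at 0.427-fold in animal 6337. In animal 5904 the dap spike-in was higher in the tumour arrays on all 3 chips, by 3.55-fold to 4.76-fold. The lys spike-in was higher there by 2.51-fold to 4.91-fold. The thr spike-in was higher there by 2.11-fold to 5.02-fold. For all 3 spike-ins the adjacent array of 5904 stood apart, as the lowest of the 6 on each chip (dap on the human chip 495, against 1960 to 4888 on the other 5 arrays). In animal 6361 the 18S ribosomal RNA probe sets were higher in the tumour arrays by 2.86-fold (mouse chip) and 3.00-fold (human chip). The dap, lys and thr spike-ins are poly-A controls of the platform, added to the RNA before labelling, and the labels do not give the amounts. The phe spike-in, of the same kind, was higher in the tumour arrays of 5904 by 1.90-fold (mouse chip) to 4.42-fold (human chip). In animal 6337 all of these spike-ins were lower in the tumour arrays on every chip, at 0.405-fold to 0.632-fold. Groups of 3 animals are too small for a test of single outlying samples.

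For the number of genes past the threshold, the 10 splits of the 6 tissues into 3 and 3, fitted with the animal block, are too few for a share under 0.05. The 3-chip average gave 81 genes and the highest other split 13, and among the 4 splits that part all 3 pairs, as the real one does, the highest other gave 0. The remaining 6 splits each part only 1 pair and keep the other 2 pairs together. The human chip gave 68 probe sets and the highest other split 0, and the rat chip 1 against 0. The mouse chip gave 0 in all 10 splits. Of the 10 splits, 1 (the real one) reached the real count on the human chip, on the rat chip and in the average.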

How the results depend on the processing

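Settings named as deposited, the pair of 5904, tissues averaged per animal and lists of single chips or of 2 chips were chosen after seeing the data, all others before. The cause of a move was not tested unless fewer animals or genes explain it. Of the 81 genes in the 3-chip average all kept their sign wherever they were tested, and EGR1 passed in all 17 alternatives (adjusted p 1.52e-23 to 0.0402). The call held in 3 of 16 alternatives for PGK1, 3 of 17 for SEC61B, 4 of 17 for COL4A1, 4 of 16 for ELOVL6, 5 of 16 for ASS1 and NINJ2, 5 of 17 for CP, 8 of 16 for CERS2, 8 of 17 for CYP2E1 and ETFB, and in 11 to 16 for the other named genes past the threshold. Genes past the threshold numbered 51 with pseudocount 1, 39 with no filter, 15 with no replicate block (unpaired), 18 without trend, 32 with the mean of probe sets, 2 without the human chip, 31 without the rat chip, 26 with mouse arrays as deposited, and 33 to 55 without 1 animal, of which 28 to 42 were shared. On the human chip there were 18 with no filter, 29 with the stricter filter, 31 with no block, 0 with no trend and 77 to 233 without 1 animal. The rat chip gave 5 with quantile normalization, 0 with pseudocount 1, 4 with the median pseudocount, 5 with no filter, 0 with the stricter filter, 0 with no block, 0 with no trend and 7 to 44 without 1 animal. The mouse chip gave 2 with the median pseudocount, 11 as deposited and 11 to 157 without 1 animal; the other mouse alternatives gave 0.

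The 2-fold counts were 244, 66 and 95 with the median pseudocount (human, rat, mouse), 891, 424 and 614 with no filter, 214, 64 and 95 with the stricter filter. With 1 animal left out, where only 2 must agree, they were 1939 to 2076, 862 to 983 and 1141 to 1485. In the average they were 26 with pseudocount 1, 10 with the median, 11 with the mean of probe sets, 50 without the rat chip, 38 without the mouse chip, 40 for genes on at least 2 chips, and 50 to 71 without 1 animal. Genes that differed between chips numbered 0 to 8 without 1 animal. Lists past the threshold numbered 0 with an estimated correlation, 0 in fry, 2 without the human chip, 4 on the rat chip alone, 0 on the mouse chip alone and 1 to 4 without 1 animal. With no replicate block cell cycle and glycolysis lost their call (adjusted p = 0.0511 each), and the other 5 lists kept theirs. The bright shares were 0.179%, 0.0800% and 0.114% (human, rat, mouse) with the B. subtilis threshold, where human minus mouse reversed from -0.108 to 0.0655. With tissues averaged per animal, human minus rat (0.646) and rat minus mouse (-0.754) lost their call (exact test, adjusted p = 0.375 each), since 3 animals allow no p under 0.25. Correlations of human and rat, human and mouse, and rat and mouse chips were 0.0649, 0.0615 and 0.0397 with no filter and 0.287, 0.247 and 0.172 with the stricter filter, and without 1 animal 0.0973 to 0.127, 0.072 to 0.0956 and 0.0349 to 0.0948.

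Direction also reversed for lists and genes that had not been called. List medians without 1 animal ran from -0.500 to 0.0552 (fetal liver, reversed without 5904), -0.223 to 0.00332 (mitochondrial respiratory chain, 5904), -0.241 to 0.227 (B cells, 6337), -0.155 to -0.0202 (chaperones, 6337), -0.142 to 0.172 (heat shock, 6337) and -0.00534 to 0.192 (proteasome, 6337). Without the human chip heat shock had -0.194 and the proteasome -0.0140, and without the rat chip B cells had -0.302, cholangiocytes -0.132 and chaperones -0.0305. Without the mouse chip the respiratory chain had 0.0342, and without the mouse-chip pair of 5904 chaperones had -0.0352. For chaperones the direction of camera turned while the median stayed negative. Over genes on at least 2 chips B cells had -0.174. On the human chip alone B cells had 0.0440, cholangiocytes -0.169 and the respiratory chain -0.0152, and on the rat chip alone endothelium had 0.118 and the respiratory chain -0.0708. Of these single-chip medians, all but that of cholangiocytes were opposite in sign to camera. On the mouse chip alone medians were 0.0681 (fetal liver), 0.177 (interferon), -0.138 (cholangiocytes), 0.0552 (chaperones), -0.0522 (heat shock) and -0.228 (proteasome).

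Without 1 animal, ALB ran from -0.367 to 0.0965 (above 0 without 5904, at 0.0310, and without 6361), KHK from -0.748 to 0.00657, ZNRF3 from -0.793 to 0.0191, CORO1A from -1.05 to 0.0534, GATA4 from -0.00643 to 0.513, ONECUT1 from -0.132 to 0.843 and TFF1 from -0.0618 to 0.646. ALB had 0.139 without the mouse chip and 0.0483 without the mouse-chip pair of 5904, ZNRF3 0.0914 without the human chip, and MMRN2 0.0544 with the mean of probe sets. Without the mouse chip PCK2 had 0.00540, CD2 -0.0685 and SDC1 0.184. Over all named genes and alternatives of the 3-chip average, 1624 results kept direction and side of the threshold, 158 lost the call, 14 gained it and 15 reversed. On single chips 235 kept both, 24 lost and 51 gained the call, and for lists 282 kept both, 52 lost and 9 gained the call and 25 reversed. Results that kept both include genes and lists that were not called and stayed so, while only called ones can lose a call. These totals therefore do not say how often a call held. The deposited signals hold no background value, so what signal over background limits was not measured.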

Other observations

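Tests in this part chosen only after the result was seen were those of single-chip lists, of the heat shock list, of the ribosomal list against random lists, and of the poor mouse array, although leaving out each animal was planned. The demand that a value also exceed the SD between animals was applied after the values had been seen. Further genes past the threshold in the 3-chip average, named after their values were seen, include regulators and carriers not described so far. Lower in carcinoma were KLF9 (-1.35, adjusted p = 0.00019) and BCL6 (-1.30, adjusted p = 0.000221), both transcription factors, NFKBIA (-1.31, adjusted p = 0.00057), the inhibitor of NF-kappa-B, MAF (-1.36, adjusted p = 0.00119), CLU, clusterin (-1.31, adjusted p = 0.00262), and ID3 (-1.30, adjusted p = 0.0267). Higher were RAN (1.24, adjusted p = 0.00119), the nuclear transport GTPase, BZW2 (1.26, adjusted p = 0.00183), EIF2S2 (1.10, adjusted p = 0.00302), an initiation factor subunit, TUFM (1.07, adjusted p = 0.0197), the mitochondrial elongation factor, and TOMM20 (0.91, adjusted p = 0.0471), of the mitochondrial import pore. Their results under the alternatives were not examined gene by gene, and they enter only the totals given for the 81 genes.

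On the human chip alone, 9 lists passed camera with the preset correlation. Cell cycle genes had a median of 0.61 (adjusted p = 2.86e-06 over 60 genes), ribosomal proteins of 0.48 (adjusted p = 2.06e-10 over 50), heat shock proteins of 0.45 (adjusted p = 0.0123 over 23) and the proteasome of 0.26 (adjusted p = 0.0206 over 28). Lower there were fatty acid oxidation (median -0.29, adjusted p = 0.0137) and xenobiotic genes (-0.23, adjusted p = 0.0137), beside plasma proteins, urea cycle and acute phase genes. On the rat chip 4 passed, among them macrophage markers (median -0.51, adjusted p = 0.0414), and on the mouse chip 0. No list passed on any chip with an estimated correlation (adjusted p of at least 0.434 on the human chip, 0.684 on the rat chip and 0.648 on the mouse chip), and whether a list differs between chips was not tested.

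In a first pattern, that of lower early-response genes, EGR1, JUNB, KLF9 and NFKBIA had been seen before a list of 46 early-response genes was written. Of the 24 others that were tested, 1 was past the threshold in the 3-chip average, FOS (-1.21, adjusted p = 0.0064, lower in 2 of 3 animals). These 24 genes had 19 negative and 5 positive differences. Their median of -0.17 was just below the 2.5th percentile of 10000 random lists matched on signal (-0.16), by less than the SD of 0.25 between animals, and camera gave p = 0.000808 with the preset correlation and p = 0.0787 with an estimated one, so chance selection of a few genes stays open for the wider class. Array scaling is argued against as the cause for EGR1, which had -2.83 under quantile normalization. Tissue handling that differed between tumour and adjacent liver may also lower these genes, and the heat shock list, at a median of 0.0501 with members going both ways, does not decide it. The actin 3'/5' signal ratio, usually read as a sign of RNA quality, was lower in tumour in 3 of 3 animals on the human chip and in 2 of 3 on the rat and on the mouse chip. For the same 6 tissues it ran from 0.230 to 0.590 on the human chip, 1.84 to 2.87 on the rat chip and 0.813 to 1.80 on the mouse chip. Its level thus depended on the chip, which does not bear on tumour against adjacent liver within a chip. Within chips the ratio was mostly lower in tumour, but not in every animal on the rat and mouse chips. The ratio therefore does not decide on RNA quality here. Handling stays open, and a biological difference between tumour and liver is likewise open.

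Higher ribosomal protein genes are the second pattern. Their median of 0.41 exceeded all but the highest 2.5% of 10000 random lists matched on signal (limit 0.27), but by less than the SD of 0.72 between animals. Genes of the random lists were drawn singly, while the ribosomal list had an estimated correlation of 0.47, so the limit may be too narrow. Array scaling or brightness therefore stays open. Under quantile normalization the list median was 0.28, and the list kept its call at the preset correlation. The median was above 0 in 2 of 3 animals and on 2 of 3 chips, between what an effect of 1 animal or 1 chip and a shared effect were set to show. With the larger sets of each chip alone the median was 0.48 (human, 48 of 50 higher), 0.71 (rat, 35 of 40) and 0.15 (mouse, 25 of 40).

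Low correlation between chips, which different animals on the same chip also showed, is the third pattern. In the brightest 991 genes the mean r over the 3 pairs of chips was 0.39, against 0.109 in all 4953 genes and 0.00753 in the dimmest 991, and 53 of the 81 genes past the threshold were among the brightest 991. Signals near the noise floor may therefore be a cause. The poor mouse array of animal 5904 is argued against as the whole cause, since r was only 0.138 between human and rat chips. Its part in the low r with the mouse chip stays open. Without that animal r went from 0.111 to 0.0956 for human and mouse chips (95% interval 0.068 to 0.123). For rat and mouse chips it went from 0.0776 to 0.0613. Human and rat chips also fell, from 0.138 to 0.0973, so loss of the animal cannot be told from loss of its mouse array. Human and mouse chips had 0.0912 without 6337 and 0.0720 without 6361, and rat and mouse chips 0.0948 and 0.0349. Probe sequence that differs from woodchuck was not tested, as woodchuck sequence was not compared with the probes.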
